A study of Gossypium hirsutum with 6 samples.

How the data were processed

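Leaf RNA of upland cotton (Gossypium hirsutum) was measured by sequencing of poly-A selected RNA in 6 libraries. Per the labels, 3 came from transgenic lines whose titles carry the name of the FPF1 gene (flowering promoting factor 1) and 3 from the wild type. The labels do not say whether the transgenic libraries came from lines with more or with less FPF1, and they do not pair the cotton names of FPF1 or NF-YA3 with gene identifiers. They also do not say whether the replicates of a group were separate plants or lines, so each p measured only the spread between these samples, which may be partly technical. The protocol text names 2 library kits and gives no batch, date or time of collection.

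The authors deposited 1 table of 72761 genes with a value in FPKM (fragments scaled to transcript length and to all mapped fragments) for each library. The smallest value, 1e-04, stood where no expression was estimated and was read as 0. The authors also deposited a fold change, which was the ratio of the mean FPKM of the transgenic libraries to that of the wild type, and its log2. The deposited p-value and q-value columns, per the file headers the authors' p and adjusted p, came with no name of the test behind them. The aligner, the counting program, the genome build and the annotation were not given in the sources used here, nor were the use of the strand and the handling of reads that match several genes. Cotton has an A and a D subgenome, so reads of homeologs and of close paralogs may be shared between identifiers. Protein descriptions, GO terms and KEGG pathways came from the deposited table. Chromosome and gene order were read from the identifiers, and coordinates were not used here.

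Read counts were not analysed here, since the table holds FPKM alone, so the counting depth behind each value is unknown and tests that need counts were not run. Relative depth was estimated from values under 0.15 FPKM, where the ratios of single genes between libraries pile up at the ratio of the depths. Deposited FPKM were used without further scaling, since each already contains a library size factor.

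Differential expression was tested with limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with an intensity trend and robust estimation (limma-trend), two-sided, without covariates. Genes with a mean of at least 1 FPKM in at least 1 group were tested, and p was adjusted by the Benjamini-Hochberg method over all genes tested. A gene was called at an adjusted p under 0.05, and a second count asked for at least a 2-fold change. Positive log2 fold changes mean higher levels in the transgenic libraries. Because of the pseudocount of 1, fold changes of genes near 0 in a group are smaller than the ratio of the levels, and for genes listed at 0 throughout a group the levels are given in place of a fold.

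The groups, the comparison, the test, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The 25 gene lists were regular expressions searched in the protein descriptions. They covered the FPF1 family, NF-Y subunits, phytochrome and PIF signalling, HD-ZIP class II, auxin, gibberellin, brassinosteroid, ethylene, jasmonate and abscisic acid with LEA proteins, flowering time, the circadian clock, expansins and xyloglucan endotransglucosylases, pectin and cellulose modification, photosynthetic light reactions, defence, phenylpropanoids and flavonoids, gossypol and terpenes, chaperones, leaf senescence and cytosolic ribosomal proteins. The remaining lists held markers of other tissues, namely dividing cells, the secondary wall of xylem, floral organs, and epidermis with cuticle. Some members were sought only by gene-name tags, which the protein descriptions read here did not carry. Such genes, among them LNK, HFR1, COP1, HY5 and FD, could not be found by the lists. For each list the members called were counted with p adjusted over all genes tested and adjusted over the list alone. The 24 lists with enough tested members were compared with all other genes by camera with a preset correlation of 0.01, two-sided, adjusted over the lists. Camera with an estimated correlation and fry were run beside it, and fry tests whether the members of a list move one way, or change at all, against no change and not against other genes. With an estimated correlation, camera also works with the few residual degrees of freedom of 6 libraries. A call lost there does not by itself show correlated genes.

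Named genes were chosen by a rule in 5 parts. These were every tested FPF1 family gene, every called NF-YA gene, and the 5 largest rises and 5 largest falls among described genes with a mean of at least 1 FPKM and no overlap between the groups. The last parts were the called member of each list with the smallest adjusted p in each direction, and every gene behind a count of 5 or fewer. Families within the lists, LNK genes, the sets of morning and evening clock genes, of Calvin cycle and photorespiration genes and of phloem markers, the division of xylem and phloem genes by level, and 10 examples from these families (GH_D10G0420, GH_D07G1797, GH_A11G0155, GH_D08G0525, GH_D01G2395, GH_D10G2562, GH_D03G1951, GH_A01G0364, GH_A13G2454 and GH_D04G1365) were chosen after the data had been seen.

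GO and KEGG terms with 10 to 500 tested members were tested by a one-sided Fisher's exact test, for rising and falling genes apart, against the tested genes that carry any term of the same vocabulary. Shares of called genes in the A and D subgenomes were compared by a two-sided Fisher's exact test. The deposited fold changes and q-values were compared with the fitted ones.

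The alternatives were median-of-ratios and upper quartile scaling, no filter, a filter of at least 1 FPKM in at least 3 libraries, a pseudocount of 0.1, no robust estimation, the replicate number as a block, an adjusted p under 0.01, a test against a fold of 1.5, other term sizes and backgrounds, and leaving out each library in turn. Tested on simulated data with the spread of these libraries, the procedure recovered 12%, 64%, 94% and 100% of genes changed 1.5, 2, 4 and 8-fold, 50 genes each, and 6 unchanged genes were called, 4.26% of the calls. With no change simulated it called 0 genes and 0 lists. Genes were simulated independently of each other, so this does not check the list test where genes are correlated. The estimated correlation reached 0.494, in the leaf senescence list. Changed genes were drawn from genes above a level higher than the filter, so recovery at lower levels was not measured. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used for placement tests, bootstraps of medians over the genes of a set (10000 resamples) and figures.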

Results

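Leaf transcripts were measured in 3 libraries of FPF1 transgenic lines and 3 of wild-type cotton. The study concerns FPF1 in shade avoidance, the elongation response of plants to neighbours, and an NF-Y transcription factor, NF-YA3, as its partner, so the comparison addresses which leaf transcripts differ between the transgenic lines and the wild type. Each library had 52037 to 53560 genes above 0, and the FPKM of a library summed to 909817 to 933688. Relative depth was 1, 0.990 and 1.14 in the transgenic libraries 1 to 3 and 1.23, 1.28 and 1.19 in the wild-type libraries, as estimated from the smallest values. The total number of reads is unknown. In a principal component analysis, the component with 50.8% of the variance separated the groups, and the next, with 22.6%, separated wild type 2 from wild type 3. Pearson correlations across genes, which are not independent replicates, were 0.932 to 0.972 within groups and 0.907 to 0.943 between them.

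The leaves of the transgenic lines carried abundant transcript of an FPF1-like gene that was near 0 in the wild type. Genes for secondary cell walls and for phenylpropanoid and flavonoid synthesis rose, 28 of 64 and 54 of 206 tested members, with none falling. Of the 28 secondary wall rises, 24 had a mean under 1 FPKM in the wild type. Without transgenic 2 the rises in these lists numbered 6 and 5. Clock genes such as GIGANTEA and light-harvesting genes fell, among them 22 of 39 chlorophyll a-b binding genes, while 8 of 12 CONSTANS-LIKE 9 genes rose (7 after rescaling). Of 43837 genes tested, 2500 were called, 1720 higher and 780 lower in the transgenic libraries, and 1292 of them changed at least 2-fold (880 higher, 412 lower). In all 2500 the groups did not overlap, as in 30.1% of all tested genes, where chance gives 10% with 3 against 3. At an unadjusted p under 0.05 there were 10524 genes.

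Rises made up 68.8% of the calls as deposited, but 54.8% of 2200 calls after median-of-ratios scaling and 57.3% of 2262 after upper quartile scaling, so the excess of rises depended on scaling. Fewer genes were called without transgenic 2 (289), transgenic 3 (803) or wild type 1 (420).

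GH_D02G0524 on chromosome D02, described as flowering-promoting factor 1-like, stood at 133, 199 and 195 FPKM in the transgenic libraries and at 0, 0 and 0.467 in the wild type (175 ± 37.1 against 0.156 ± 0.270, mean ± SD, n = 3 each, as for all other levels given with ±). Its log2 fold change was 7.25 with a standard error of 0.214 (adjusted p = 3.7e-05), or 9.92 with a pseudocount of 0.1, and it was called in every setting tried. The values do not separate transcripts of a transgene from those of the resident gene. Of 12 FPF1 family genes listed, 5 were at 0 in every library and 2 were expressed enough to be tested. The other tested member, GH_D10G1881 (FPF1-like 3), was at 0, 0 and 0.341 FPKM in the transgenic and 2.84, 2.92 and 0 in the wild-type libraries and was not called (adjusted p = 0.231), though it was called without wild type 3 (adjusted p = 0.0159). The family was too small for the list test, and adjusted over the list alone 1 member rose.

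The NF-Y subunit list, of trimeric transcription factors that bind CCAAT boxes, had 3 of 53 tested members higher and 0 lower, the same numbers as adjusted over the list alone. Among 25 tested NF-YA genes only GH_D01G1407, NF-YA9-like, was called, at 81.4 ± 14.2 against 38.2 ± 4.05 FPKM (log2 1.06, standard error 0.148, adjusted p = 0.0125). The call ended without transgenic 2 (adjusted p = 0.0703). The gene described as NF-YA3-like with the largest difference, GH_D04G0107, had a log2 difference of 0.51 and an adjusted p of 0.166. Both other rises were NF-YC2-like genes, GH_D11G3340 (log2 0.74) and GH_A01G0969 (0.61), the second of which was not called after median-of-ratios scaling (adjusted p = 0.0526). None of the 3 was called without transgenic 2. The NF-Y list was not called (adjusted p = 0.810, direction below other genes), with a median of 0.043 that turned negative after scaling.

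**Figure D1:**
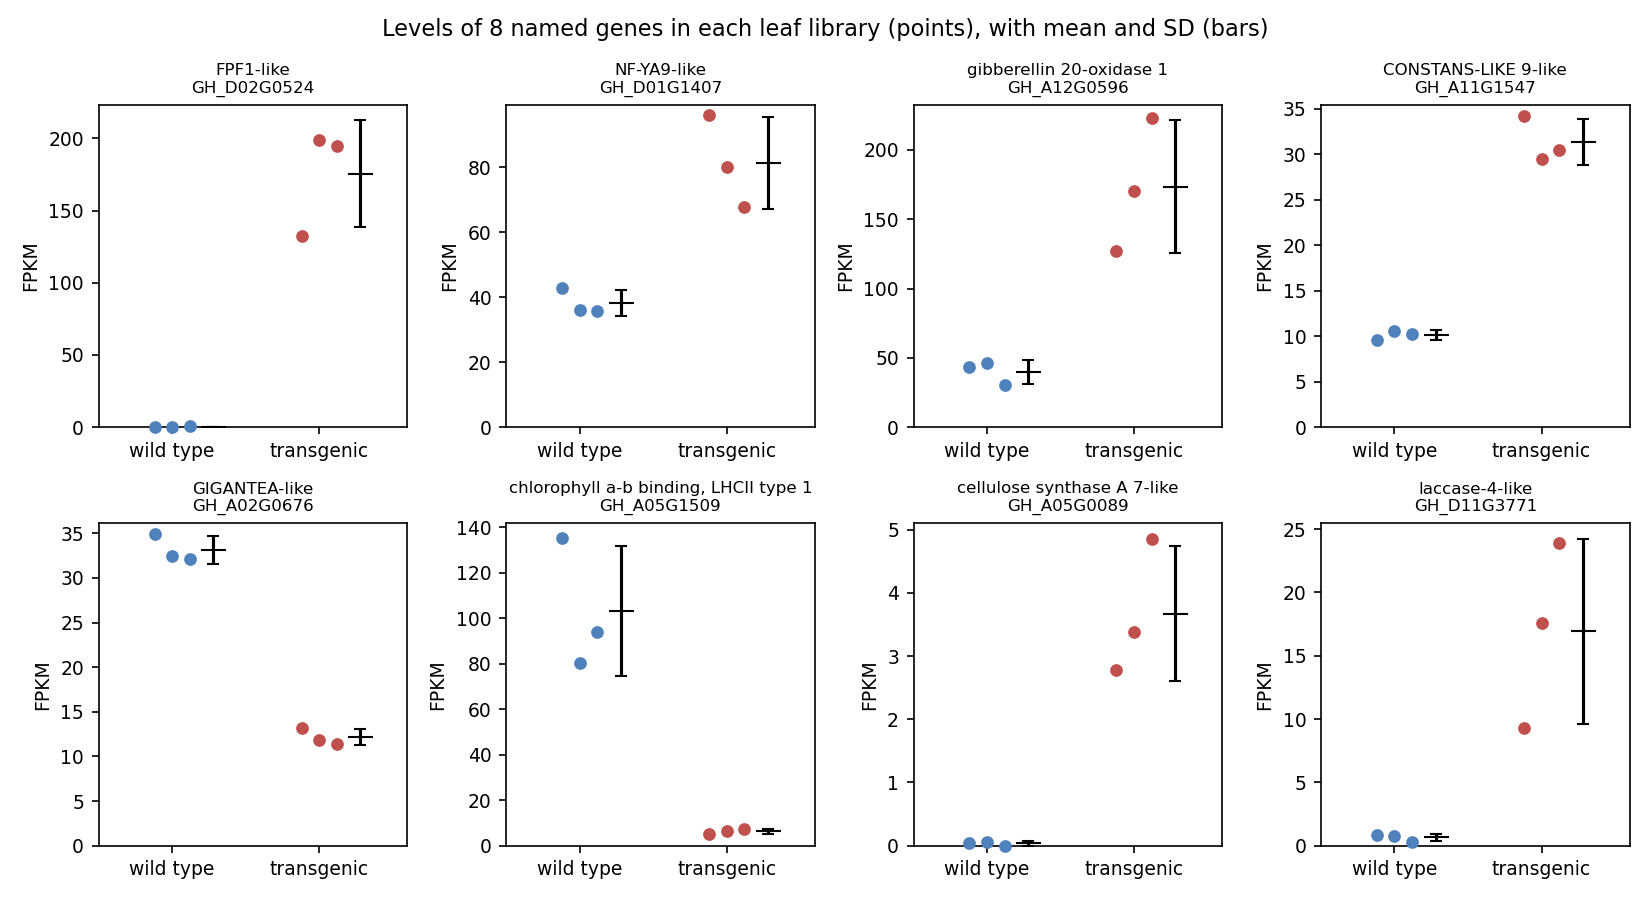
Levels in FPKM of 8 named genes in each library (points, blue for wild type and red for transgenic), with the mean and SD of 3 libraries (bars), each panel on its own linear axis from 0. The FPF1-like gene stood at 133 to 199 FPKM in the transgenic libraries and at most 0.467 in the wild type.

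Other genes moved from near 0 to clear expression. GH_A07G1555, neomenthol dehydrogenase-like, rose from 0, 0.106 and 0.186 FPKM to 242, 215 and 129 (log2 7.44, standard error 0.229, adjusted p = 3.97e-05). GH_A13G1414, a carboxymethylenebutenolidase homolog, rose from 0.205 ± 0.356 to 26.7 ± 5.86 FPKM (log2 4.54). GH_A07G1557, salutaridine reductase-like, was listed at 0 in the wild type and at 29.03, 19.03 and 18.56 FPKM in the transgenic libraries. GH_A13G2237, described as a homolog of VPS32, a protein of endosomal sorting, was listed at 0 in the wild type and at 13.4, 21.6 and 19.4 FPKM. These calls held without any 1 library, and so did the fall of GH_A02G0223, a plasma membrane ATPase 10-like gene, from 19.3 ± 5.48 to 0.0772 ± 0.134 FPKM (log2 -4.20, adjusted p = 0.000485). The remaining large falls varied widely within the wild type. GH_D01G0721, a 2S seed storage protein, stood at 33.0, 116 and 4.69 FPKM there and at most 0.163 in the transgenic libraries (log2 -4.71, adjusted p = 0.0364). GH_D10G1961, beta-D-xylosidase 1-like, fell by 4.54 (adjusted p = 0.0427), GH_D03G1239, a 21 kDa protein, by 4.08 (adjusted p = 0.0139) and GH_A03G1210, an eIF5A-2-like translation factor, fell by 4.05 on the log2 scale (adjusted p = 0.0390). None of these 4 was called without transgenic 2 or without wild type 1, where adjusted p reached 0.0730 to 0.162 over the libraries left out. The first, second and last were also lost without transgenic 1 or transgenic 3, and the second and last without wild type 2. All 4 were lowest in wild type 3. All but GH_A03G1210 were highest in wild type 2, such as GH_D10G1961 at 110, 180 and 9.75 FPKM in wild type 1 to 3. The LEA protein gene GH_A09G1438, not called, stood at 10.4, 79.3 and 2.29 FPKM there and at 0 in the transgenic libraries. Wild type 2 and 3 also lay apart in the principal component analysis, and a difference between the wild-type samples was not tested.

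Genes of the xylem secondary wall rose as a list, with 28 of 64 tested members higher and none lower (36 and 0 adjusted over the list alone). The median log2 fold change was 0.87 and the list test gave an adjusted p of 1.05e-13, but an adjusted p of 0.579 with an estimated correlation. GH_D11G3771, laccase-4-like, an enzyme type that polymerises lignin, rose from 0.654 ± 0.298 to 16.9 ± 7.32 FPKM (log2 3.36, standard error 0.324, adjusted p = 0.00474). The cellulose synthases CesA4, CesA7 and CesA8, which make the secondary wall, rose in 9 of 10 tested genes. Among them GH_A05G0089 (CesA7-like) rose from 0.0345 ± 0.0323 to 3.67 ± 1.07 FPKM and GH_D08G0525 (CesA4-like) from 2.12 ± 0.129 to 9.51 ± 2.30. Of the 28 rises, 14 were shared with the pectin and cellulose list and 1 with the phenylpropanoid list. In the wild type 29 of the 64 members, and 4 of the 28 that rose, had a mean of at least 1 FPKM. The other 35 members passed the filter only through the transgenic libraries, so a positive difference was largely built in for them. For 50 members with a mean over all 6 libraries of at least 1 FPKM the median was 0.90. It was 0.49 at 2 FPKM or more (32 genes) and 0.45 at 3 FPKM or more (29 genes). The number of rises was 6 without transgenic 2, 13 without transgenic 3 and 9 without wild type 1.

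Phenylpropanoid and flavonoid synthesis rose in 54 of 206 tested genes with no falls (81 and 4 adjusted over the list alone), a median of 0.46 and an adjusted p of 2.46e-07. With an estimated correlation the adjusted p was 0.591. Chalcone synthases or isomerases, at the entry to flavonoids, rose in 7 of 12 genes (6 after rescaling), and phenylalanine ammonia-lyases, at the entry to the pathway, in 4 of 9. GH_D09G2598, 4-coumarate--CoA ligase-like 9, rose from 0.224 ± 0.0530 to 8.996 ± 3.096 FPKM (log2 2.98, adjusted p = 0.00351). GH_D01G2395, a phenylalanine ammonia-lyase, rose from 18.9 ± 4.72 to 94.5 ± 30.4 FPKM, a call lost without transgenic 2 (adjusted p = 0.0555). The list had 5 rises without transgenic 2, 24 without transgenic 3 and 8 without wild type 1.

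Pectin and cellulose genes had 25 rises and 2 falls among 206 (39 and 4 adjusted over the list alone), with an adjusted p of 1.26e-05 for the list and an adjusted p of 0.579 with an estimated correlation. Fasciclin-like arabinogalactan proteins rose in 7 of 30 genes. The falls were GH_A09G1425, a polygalacturonase inhibitor (log2 -0.92), and GH_A13G2071, pectin acetylesterase 12-like (log2 -2.36). Epidermis and cuticle genes had 35 rises and 4 falls among 241 (59 and 7 adjusted over the list alone, adjusted p = 0.000995). For that list the adjusted p was 0.660 with an estimated correlation. GH_A03G1544, a GDSL esterase, rose from 0.272 ± 0.0489 to 10.9 ± 2.09 FPKM (log2 3.21, adjusted p = 0.000426). GH_A12G0543, non-specific lipid-transfer protein 2, fell from 337 ± 100.8 to 75.6 ± 21.8 FPKM (log2 -2.14, adjusted p = 0.01002). The other falls were GH_D05G2762 and GH_D05G2498, both GDSL esterases, and GH_D09G2266, a lipid-transfer protein (log2 -0.95, -1.15 and -0.84). Without transgenic 2, transgenic 3 or wild type 1, rises numbered 7, 11 and 10 for pectin and cellulose and 5, 15 and 11 for cuticle. The 6 falls were all lost without transgenic 2 or wild type 1, with adjusted p up to 0.158 over the libraries left out.

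**Figure D2:**
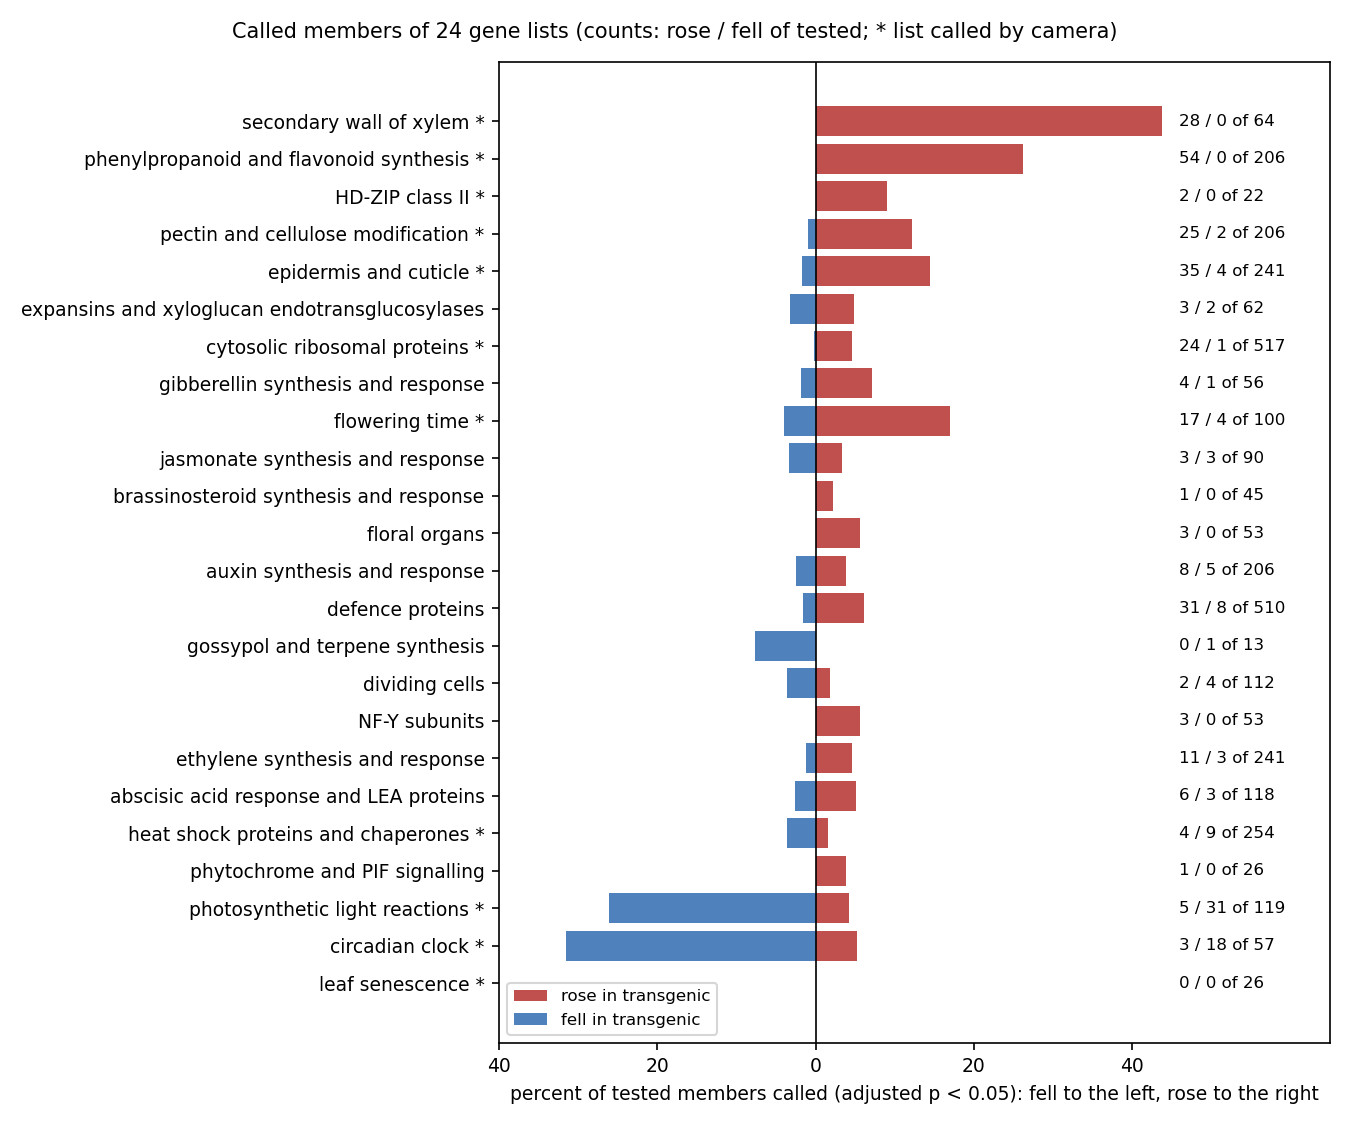
Percent of tested members called in 24 gene lists, falls to the left in blue and rises to the right in red, with the counts at the right and a star where camera called the list with its preset correlation. Secondary wall genes had 28 rises of 64, and clock genes 18 falls of 57. None of the stars held with an estimated correlation, a version that also leaves few degrees of freedom.

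Circadian clock genes had 18 falls and 3 rises among 57 (23 and 4 adjusted over the list alone), with a median of -0.31 and an adjusted p of 1.61e-09. The adjusted p was 0.253 with an estimated correlation. All 7 APRR5 and all 4 GIGANTEA genes fell, both components that peak late in the day. The other falls of the list were in genes outside the families named here, which were not sorted by daily phase. GH_A02G0676, GIGANTEA-like, fell from 33.1 ± 1.54 to 12.2 ± 0.924 FPKM (log2 -1.38, standard error 0.0998, adjusted p = 0.00170), and GH_A11G0155 (APRR5) from 22.8 ± 2.30 to 4.70 ± 1.07. All 9 LNK genes, partners of morning clock factors that the list had left out, fell with a median of -1.34. None of 12 REVEILLE genes was called, with a median of 0.013 that turned negative after scaling, nor were the 3 LHY genes (median -0.45). The rises were EARLY FLOWERING 3-like genes, GH_A07G0243 (log2 0.79), GH_D07G0249 (0.48) and GH_A07G0242 (0.41). After either scaling only GH_A07G0243 was called, and none of them without transgenic 2, transgenic 3 or wild type 1 (adjusted p up to 0.176). The falls numbered 9 without transgenic 2, 11 without transgenic 3 and 9 without wild type 1.

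Photosynthetic light reactions had 31 falls and 5 rises among 119 (42 and 12 adjusted over the list alone), a median of -0.21 and an adjusted p of 5.50e-09. The adjusted p was 0.591 with an estimated correlation and 0.0728 by fry. Chlorophyll a-b binding genes, which hold the pigments of the light-harvesting antennae, made up 22 of the falls, with a median of -1.08 over 39 genes. GH_A05G1509, of the LHCII type 1, fell from 103 ± 28.6 to 6.28 ± 1.02 FPKM (log2 -3.81, standard error 0.204, adjusted p = 0.000426), and GH_D10G0420 of the same type from 352 ± 85.7 to 41.6 ± 8.34. Of 60 photosystem subunits and factors, 9 fell and 3 rose. The rises were the small RuBisCO subunits GH_A11G1702 (from 9.16 ± 0.534 to 74.3 ± 43.3 FPKM, log2 2.75, adjusted p = 0.00933) and GH_D11G1742 (log2 2.15), GH_A01G2050 (photosystem II 22 kDa protein, 1.06), GH_D07G0173 (a photosystem I antenna protein, 1.40) and GH_D02G2046 (HCF136, an assembly factor, 0.54). All but GH_A11G1702 were lost without transgenic 2 or wild type 1, with adjusted p up to 0.133 over the libraries left out. The falls numbered 13 without transgenic 2, 15 without transgenic 3 and 13 without wild type 1.

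Flowering time genes had 17 rises and 4 falls among 100 (26 and 9 adjusted over the list alone, adjusted p = 0.0110). This list's call was lost without wild type 2 (adjusted p = 0.137), and the adjusted p was 0.591 with an estimated correlation. CONSTANS-LIKE 9, a repressor of flowering in Arabidopsis, made up 8 of the rises, or 7 after either scaling. GH_A11G1547 rose from 10.1 ± 0.507 to 31.4 ± 2.51 FPKM (log2 1.54, standard error 0.102, adjusted p = 0.00136), and GH_D07G1797 from 1.86 ± 0.354 to 11.99 ± 1.38. Other CONSTANS-like genes fell, namely GH_D08G0948 (COL7, log2 -1.04), GH_A08G0265 (COL6, -0.96), GH_D08G0281 and GH_A08G0963 (COL5, -1.15 and -0.91). These 4 falls ended without transgenic 2 (adjusted p 0.0555 to 0.118 at their largest), and 3 of them, COL7 aside, also without wild type 1. Without transgenic 2, transgenic 3 or wild type 1, rises numbered 6, 9 and 8.

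**Figure D3:**
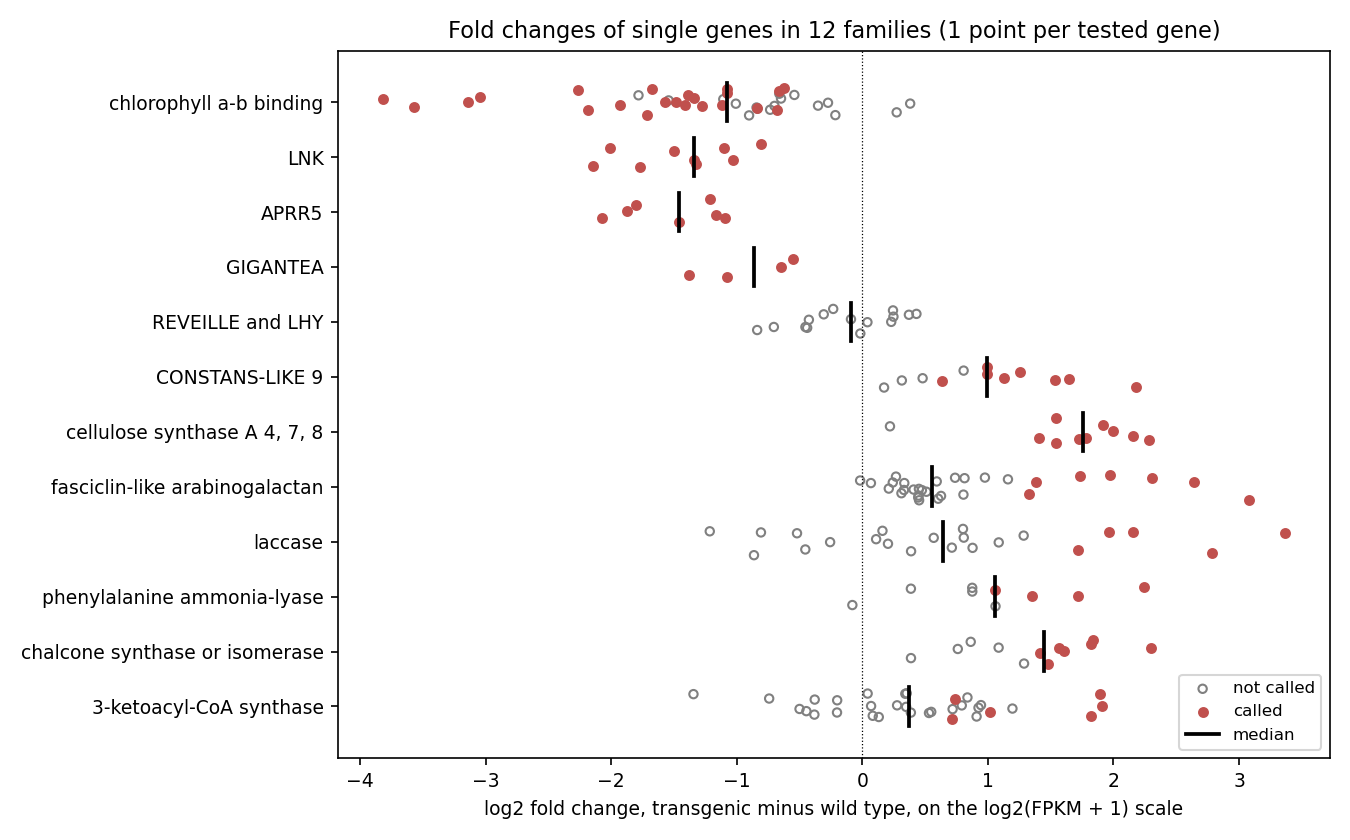
Log2 fold changes (transgenic minus wild type, on the log2(FPKM + 1) scale) of single tested genes in 12 families, filled where called, with the median as a bar. All LNK, APRR5 and GIGANTEA genes lay below 0 and were called, while no REVEILLE or LHY gene was called.

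Among genes of shade and growth signals, HD-ZIP class II genes, which respond to shade in Arabidopsis, had 2 rises among 22 (4 adjusted over the list alone) and a median of 0.45. The list's adjusted p was 0.0276, against an adjusted p of 0.591 with an estimated correlation, 0.0576 without transgenic 2 and 0.137 without wild type 2. GH_A12G1123 (HAT3-like) rose from 54.8 ± 15.5 to 129 ± 30.7 FPKM (adjusted p = 0.0338) and GH_A08G1926 (HAT4-like) from 48.2 ± 5.59 to 77.1 ± 9.83, the latter not called after scaling (adjusted p up to 0.0625). The phytochrome and PIF signalling list could not find genes sought only by gene-name tags, so it covered only part of this signalling. Of its 26 tested genes only GH_A05G2264, cryptochrome-1-like, rose (log2 0.68, adjusted p = 0.0162). It was also the only call adjusted over the list alone, and the list was not called (adjusted p = 0.262). None of these 3 genes was called without transgenic 2, transgenic 3 or wild type 1 (adjusted p up to 0.128), while 5 HD-ZIP class II genes rose without wild type 3.

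Gibberellin genes had 4 rises and 1 fall among 56, the same numbers as adjusted over the list alone, and the list was not called by camera (adjusted p = 0.185) but was by fry (adjusted p = 0.0188), which tests members against no change and not against other genes. GH_A12G0596, gibberellin 20-oxidase 1, which makes precursors of active gibberellins, rose from 39.9 ± 8.52 to 173 ± 48.1 FPKM (log2 2.08, standard error 0.237, adjusted p = 0.00758). GH_D08G2039, gibberellin 3-hydroxylase 1, which makes the active forms, rose from 31.5 ± 2.04 to 98.2 ± 41.0 FPKM. Both other rises were the gibberellin-regulated protein 4-like genes GH_A09G0176 (log2 2.40) and GH_D09G0170 (1.23). GH_A08G2403, a receptor like GID1C, fell by 0.72 on the log2 scale (adjusted p = 0.0432), a call that ended with each library left out in turn. Without transgenic 2 no rise was called (adjusted p = 0.0525 for the 20-oxidase), and without wild type 1 only that of the 20-oxidase, while 8 members rose without wild type 2.

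Auxin genes had 8 rises and 5 falls among 206 (13 and 7 adjusted over the list alone, list adjusted p = 0.910, with a positive median of 0.12 but a test direction below other genes). GH_A11G1232, auxin response factor 23-like, rose from 3.68 ± 1.12 to 18.5 ± 5.75 FPKM (adjusted p = 0.0107). GH_D01G1731, the auxin exporter PIN4-like, fell by 0.81 on the log2 scale (adjusted p = 0.0182), as did GH_A09G1641 (SAUR71-like, log2 -1.62), GH_A06G0045 (auxin-induced protein 15A, -1.99), GH_D11G2121 (GH3.1, -0.94) and GH_A09G2433 (IAA14-like, -0.99). Of 45 brassinosteroid genes only GH_A05G2025, BRI1 kinase inhibitor 1-like, rose (log2 1.46, adjusted p = 0.0132), also adjusted over the list alone (list adjusted p = 0.242). Ethylene genes had 11 rises and 3 falls among 241 (15 and 6 adjusted over the list alone, list adjusted p = 0.380). GH_A07G0498, the transcription factor ERF107-like, rose from 0.0136 ± 0.0235 to 9.81 ± 3.36 FPKM (adjusted p = 0.00147), a call that held without any 1 library. The falls were GH_A02G0398 (ACC oxidase homolog 1-like, log2 -0.74), GH_D11G1631 (ACC oxidase-like, -2.02) and GH_D06G1262 (ABR1-like, -1.09). The other genes named here were not called without transgenic 2 (adjusted p up to 0.173 over the libraries left out), and without wild type 1 only GH_A11G1232 and GH_D11G1631 were. The median of the ethylene list, 0.023, turned negative after scaling, where 7 members fell. Without transgenic 2, transgenic 3 and wild type 1, rises numbered 0, 2 and 2 for auxin and 2, 16 and 2 for ethylene. Without wild type 2, falls numbered 10 for ethylene and 8 for auxin and rises 4 for brassinosteroid, and without wild type 3 there were 9 ethylene falls.

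Expansins and xyloglucan endotransglucosylases, which loosen primary walls, had 3 rises and 2 falls among 62 (10 and 3 adjusted over the list alone, list adjusted p = 0.380, or 0.0443 by fry). GH_D02G1499 (XTH28-like), GH_A13G0812 (expansin A10) and GH_D11G2705 (expansin A15-like) rose by 0.86, 1.33 and 0.88 on the log2 scale, while GH_D12G2275 (XTH30-like, log2 -0.93) and GH_D12G1970 (expansin A1-like, -1.37) fell. None was called without transgenic 2 or without wild type 1 (adjusted p up to 0.126 over the libraries left out), while 6 members fell without wild type 3.

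Jasmonate genes had 3 rises and 3 falls among 90 (6 and 3 adjusted over the list alone, list adjusted p = 0.287). The rises were TIFY genes, which include repressors of jasmonate signalling, with GH_D12G0024 (TIFY4B-like) at 102 ± 8.56 against 44.5 ± 4.50 FPKM (adjusted p = 0.00497), GH_A12G0025 (TIFY4B-like, log2 0.98) and GH_A10G0431 (TIFY5A-like, 1.03), the last not called after scaling (adjusted p up to 0.0622). The falls were the 23 kDa jasmonate-induced proteins GH_D10G1390 (from 52.4 ± 6.78 to 2.93 ± 2.15 FPKM) and GH_A10G1501 (log2 -1.50), and GH_A08G1275 (MYC2-like, -1.11), a transcription factor of the jasmonate response. GH_D12G0024 and GH_D10G1390 were called without any 1 library, and the other 4 were lost without transgenic 2 (adjusted p up to 0.172 over the libraries left out), 3 of them also without wild type 1. Defence genes had 31 rises and 8 falls among 510 (36 and 9 adjusted over the list alone, list adjusted p = 0.380, or 0.0490 by fry). GH_D05G3882, a disease resistance protein, was listed at 0 in the wild type and at 10.9, 7.96 and 10.7 FPKM in the transgenic libraries. GH_D12G2631, glucan endo-1,3-beta-glucosidase 11-like, fell by 1.01 on the log2 scale, a call lost without transgenic 2, transgenic 3 or wild type 1 (adjusted p up to 0.0911). WRKY factors, which regulate defence, rose in 12 of 160 genes and fell in 1, with 6 and 9 rises after the scalings. Defence rises numbered 5 without transgenic 2, 9 without transgenic 3 and 6 without wild type 1, and falls 0, 1 and 0.

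Chaperone genes had 9 falls and 4 rises among 254 (9 and 2 adjusted over the list alone), with a median of -0.020. The list was called lower (adjusted p = 0.00628), with an adjusted p of 0.253 with an estimated correlation and 0.0722 by fry. The estimated correlation, 0.0035, was below the preset 0.01, so correlated genes do not account for the loss by camera. GH_D13G2148, heat shock factor HSF30, fell from 52.8 ± 1.83 to 21.997 ± 1.12 FPKM (adjusted p = 0.00178). The rises were GH_D06G2116 (dnaJ 10-like, log2 0.87), GH_D05G0174 (dnaJ 49-like, 1.01), GH_D04G0404 (heat stress factor A-4b-like, 0.66) and GH_D04G2015 (a chloroplast small heat shock protein, 0.54). After scaling only the first of these was called (adjusted p up to 0.0837 for the rest), and without transgenic 2, transgenic 3 or wild type 1 none was (adjusted p up to 0.161 over the libraries left out). Falls numbered 2 without transgenic 2, 4 without transgenic 3 and 2 without wild type 1. Leaf senescence genes, 26 tested, had no member called by limma, nor any adjusted over the list alone, but 7 falls without wild type 3 and 2 rises without wild type 2. Their median was -0.32 and the list was called lower (adjusted p = 0.00158). The adjusted p was 0.689 with an estimated correlation, 0.509 by fry and 0.218 without wild type 2, where the median was -0.017.

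Cytosolic ribosomal proteins had 24 rises and 1 fall among 517, none adjusted over the list alone, and a median of 0.26 (list adjusted p = 1.61e-09, adjusted p = 0.660 with an estimated correlation). Rises numbered 6 after median-of-ratios and 8 after upper quartile scaling, and 0 without transgenic 2, 2 without transgenic 3, 1 without wild type 1 and 9 without wild type 2. GH_D04G1976 (L3-2) rose by 0.70 (adjusted p = 0.0122) and GH_A07G2239 (L23-like) fell by 0.93 on the log2 scale (adjusted p = 0.0350). Neither was called without transgenic 2 or wild type 1, and the second was also lost without transgenic 1, transgenic 3 or wild type 3 (adjusted p up to 0.135).

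The remaining lists were not called by camera, nor in a direction by fry. Abscisic acid and LEA genes had 6 rises and 3 falls among 118 (9 and 7 adjusted over the list alone, list adjusted p = 0.182), a median of 0.00015 that turned negative after scaling and a mean of -0.14. This list was called lower without transgenic 1 (adjusted p = 0.0380) or wild type 3 (adjusted p = 0.00454), and 9 members fell without wild type 3. Its rises numbered 0 without transgenic 2, 2 without transgenic 3 and 0 without wild type 1. GH_D08G1529 (the receptor PYL9-like) rose by 0.72, while the zeaxanthin epoxidases GH_A11G2014 (log2 -1.18) and GH_D11G2054 (-1.25) and the desiccation-related GH_D12G0102 (-1.61) fell. Gossypol and terpene genes had 1 fall among 13 (2 rises and 3 falls adjusted over the list alone, list adjusted p = 0.296), GH_A01G0897, farnesyl pyrophosphate synthase 2-like (log2 -0.70). The median of that list was 0.071 and its mean -0.11. Markers of dividing cells had 2 rises and 4 falls among 112, the same numbers as adjusted over the list alone (list adjusted p = 0.381, median 0.060, negative after scaling). All of these were histones, with rises of the H3.2 genes GH_D13G2429 (1.39) and GH_D10G0548 (1.00, not called after scaling, adjusted p up to 0.0598) and falls of the H1-like genes GH_A13G1975 (from 623 ± 33.3 to 318 ± 16.5 FPKM), GH_D13G1936 (log2 -0.996), GH_D11G1361 (-0.64) and GH_A11G1327 (-0.47). Markers of floral organs had 3 rises among 53 (5 adjusted over the list alone, list adjusted p = 0.533). These were APETALA 2-like genes, GH_D01G2423 (0.91), GH_A01G2345 (1.18) and GH_D11G2083 (0.47), the last not called after scaling (adjusted p up to 0.0789). Without wild type 2, 2 members rose and 5 fell, and without wild type 3, 5 rose and 1 fell. Except for GH_A13G1975, none of the genes named here was called without transgenic 2 or without wild type 1 (adjusted p up to 0.171 over the libraries left out).

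Among GO terms, 84 of 2337 were enriched in genes that rose and 38 in genes that fell, and among 119 KEGG pathways 13 and 4. The tests of terms, here and below, take genes as independent, although homeologs and genes regulated together are not. Their p therefore measures no spread between libraries. Rises were enriched in secondary wall biogenesis (33 of 84 members, adjusted p = 1.23e-21), the flavonoid pathway of KEGG (31 of 142, adjusted p = 1.61e-12) and the glycine cleavage complex (9 of 14, adjusted p = 1.17e-07). Falls were enriched in light harvesting in photosystem I (28 of 52, adjusted p = 2.96e-32) and in circadian rhythm (32 of 173, adjusted p = 1.22e-20). Circadian rhythm was also enriched among rises (18 of 173, adjusted p = 0.00664, and 25 of 247 in KEGG, adjusted p = 0.000540), as was the photosynthesis pathway of KEGG (19 of 126, adjusted p = 2.75e-05, with 11 among falls, adjusted p = 0.00141). Without transgenic 2, transgenic 3 or wild type 1, 35, 77 and 42 terms and pathways were enriched, of 139 with all libraries. The shares of genes called did not differ between subgenomes, with 1208 of 21642 in A and 1286 of 22089 in D (odds ratio 0.956, Fisher's exact p = 0.284, genes not being independent replicates).

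The authors' table had 4230 genes at a q under 0.05, 2220 higher and 2010 lower in the transgenic libraries. Of the 2500 genes called here, 2104 were among them, all in the same direction. Across 43068 genes the log2 fold changes had a Pearson r of 0.955. The deposited p under 0.05 with at least a 2-fold change held 3723 genes, with q up to 0.257.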

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

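The settings for genes near 0 in 1 group were chosen only after the results had been seen. Across all settings, 34 values about the whole comparison moved and 120 did not, and 276 counts of list members moved and 474 did not. Named genes lost a call in 154 cases, gained 1 and kept their side in 564, and list tests lost 18, gained 5 and kept 337. No result of any kind changed its direction past the threshold. With the replicate number as a block, a model that spends degrees of freedom although the numbers did not pair the libraries (correlations of replicate deviations 0.0136 to 0.0740), 1532 genes were called, 1029 higher and 503 lower, of which 1327 were among the 2500. At an adjusted p under 0.01 the counts were 334 called (219 higher, 115 lower), 309 changed at least 2-fold and 48 enriched terms. Tested against a fold of 1.5 they were 178 (121 and 57), 178 and 30. Both are stricter thresholds by construction. With the correlation between genes estimated, which also leaves few degrees of freedom, 0 of 24 lists were called by camera in place of 11. Of these lists, 2 reached an unadjusted p under 0.05. Fry called 23 in either direction and 11 in 1 direction, of which 8 were among those of camera. It lost photosynthesis, chaperones and leaf senescence and gained gibberellin, expansins and defence, but tests against no change, and all tested genes had a median above 0. Leaving out each library in turn gave 289 to 2552 calls, 182 to 1561 higher and 107 to 1060 lower, 270 to 1554 changed at least 2-fold, 35 to 162 enriched terms and 8 to 12 lists. The lowest counts came without transgenic 2 (289), wild type 1 (420) and transgenic 3 (803), where 287, 404 and 726 of the genes called were among the 2500. Fewer samples can lower the counts, but as many were left in the other fits of this kind, which called 1865 to 2552, and the cause of the difference was not tested. Of 48 named calls from the first parts of the rule, 20 held in all 6 of these fits, and 28, 24 and 16 were lost without transgenic 2, wild type 1 and transgenic 3. Of 43 further genes named for small counts, 0 held in all 6, and 10 were lost after a scaling. Rises were 68.8% of calls as deposited, 54.8% and 57.3% after the scalings and 58.5% without wild type 3. The median log2 fold change of all tested genes, 0.080, was 0.0028 and 0.020 after the scalings. No filter (1678 calls), a pseudocount of 0.1 (2376), a filter by libraries (2588) and no robust estimation (2527) kept the counts within 1.5 times. Stricter levels for genes near 0 in 1 group left 14 of 78 such genes. Not run were DESeq2 size factors and its Wald test, voom, quasi-likelihood tests and library size alone, which need counts, filters in CPM, and a switch between protein annotations, of which the table held 1. Counting depth is unknown, so no floor can be given for values of 0. In the simulation, where the changed genes were among the more abundant ones, 12% of 1.5-fold and 64% of 2-fold changes were recovered. So 1.5-fold changes were mostly missed.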

Other observations

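The tests of genes near 0 in 1 group and of clock and light-harvesting genes, the set of Calvin cycle and photorespiration genes included, and the division of xylem and phloem genes by level were chosen only after their results had been seen, while the test on phloem genes and that on other splits of the samples were set before theirs. Standard errors of medians below come from resampling the genes of a set. They treat genes as independent and hold no spread between libraries.

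Genes of carbon fixation and photorespiration rose while the light-harvesting genes fell. Of 47 tested genes of the Calvin cycle and photorespiration, 21 rose and 1 fell (19 and 1 after either scaling), with a median of 0.87 and a standard error of 0.160. RuBisCO activase 2 (GH_D10G2562) rose from 13.6 ± 0.564 to 44.8 ± 4.74 FPKM, phosphoribulokinase (GH_D03G1951) from 7.62 ± 1.32 to 24.1 ± 1.38, glycolate oxidase (GH_A01G0364) from 12.5 ± 1.57 to 42.6 ± 10.7 and serine-glyoxylate aminotransferase (GH_A13G2454) from 5.23 ± 0.760 to 25.9 ± 10.4 (mean ± SD, n = 3 each), and these calls held without any 1 library. The fall was that of another RuBisCO activase gene, GH_D04G1365 (log2 -1.05, adjusted p = 0.0299), a call lost without transgenic 2, transgenic 3 or wild type 1 (adjusted p up to 0.124). The reductive pentose-phosphate cycle was enriched among rises with 14 of 34 members (adjusted p = 7.64e-09), and the KEGG pathway of carbon fixation with 34 of 192 (adjusted p = 2.74e-11).

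Suberin synthesis, which makes a barrier polymer of walls, was enriched among rises with 13 of 29 members (adjusted p = 8.49e-09), xylan synthesis with 14 of 45 (adjusted p = 2.64e-07) and cutin synthesis with 10 of 38 (adjusted p = 0.000166). Falls were enriched in sulfate assimilation with 14 of 98 members (adjusted p = 3.62e-07) and in degradation of valine, leucine and isoleucine with 14 of 163 (adjusted p = 0.000215).

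The 6 libraries can be split 3 against 3 in 10 ways. The real split gave 2500 calls and the highest of the others gave 1, so only 1 split, the real one, reached that count, but 10 splits are too few for a share under 0.05.

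Genes near 0 in 1 group, with at least 2 FPKM in all 3 libraries of the other and under 0.5 in this one, numbered 78, of which 63 were on in the transgenic and 15 in the wild-type libraries. Between consecutive genes of this kind there were 4 pairs within 5 positions, GH_A07G1555 with GH_A07G1556, the latter with GH_A07G1557, GH_A13G2237 with GH_A13G2238, and GH_D05G3882 with GH_D05G3885, and a share of 0.001 of 10000 random placements gave as many (share 0.0024 when drawn from the other called genes). Linked sequence differences between the lines, such as the insertion site or the background of the parent plants, may account for such pairs. Most of the 78 had no such neighbour. With other levels and distances the share went from 0.0001, the smallest these placements can give, to 0.1091 for pairs up to 50 positions apart. The 78 were also uneven over the chromosomes, with 9 on D13, 9 on D05 and 7 on A07 but 0 on A12 and D11. Their chi-square over chromosomes was 57.4, and a share of 0.0006 of placements gave as much (0.0005 when drawn from the other called genes). Linked differences over longer stretches may account for this unevenness too. Joint regulation of neighbours and reads shared between tandem copies stay open, since 100% of only 4 pairs went in the same direction where permuted directions gave 25% to 100%, and of 5 pairs within 5 positions, GH_A07G1555 with GH_A07G1557 added, only this 1 had informative descriptions of both genes, which differed. Other called genes also had more neighbouring pairs, 484, than any placement gave (at most 440), and no test here separates a biological effect of FPF1 on these genes from linkage.

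Clock and light-harvesting genes fell together, and the time of collection is not given, although 3 of 9 EARLY FLOWERING 3 genes rose and circadian rhythm was enriched among rises too (18 of 173 members). Of the genes taken as afternoon and evening genes, all 20 APRR5, GIGANTEA and LNK genes fell (median -1.33). Of 14 APRR1, PCL1 and ELF4 genes 1 fell, with 7 above and 7 below 0 (median -0.011). A lower share of mesophyll in the transgenic samples would lower other mesophyll transcripts too. The Calvin cycle and photorespiration set, chosen after its rise had been seen, had a median of 0.87. This lay far above -0.54, the bound at 50% of the median of the chlorophyll a-b binding genes. A lower share of mesophyll alone would not raise these genes. As their rise was known when the set was chosen, though, the comparison is no independent test of that share. A different hour of collection was tested by whether morning and evening genes moved in opposite directions, and the 15 LHY and REVEILLE genes of the morning had a median of -0.090 with a standard error of 0.176, 6 above and 9 below 0, which does not decide. The test also depended on its sets, since all 9 LNK genes, which peak in the morning in Arabidopsis but were counted as evening genes, fell, and moving them gave medians of -0.45 for the morning (standard error 0.230) and -0.51 for the evening set (0.261), or -0.20 (0.165) with EARLY FLOWERING 3 added. Further falling genes of the clock list, outside the families named here, entered neither set. As genes of neighbouring phases can fall together at another hour, collection time and an effect of the transgene cannot be told apart here, and either may underlie the falls.

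Secondary wall and lignin genes rose together. More vein tissue in the transgenic samples would raise phloem markers along with those of xylem, by at least 0.44 at the bound set beforehand. The 24 phloem genes had a median of -0.081 with a standard error of 0.112 and no call by limma. They thus did not rise with the xylem list. This does not exclude more vein tissue, since that error holds no spread between libraries and the bound rests on many xylem genes near 0 in the wild type. Since 35 of the 64 xylem genes were under 1 FPKM in the wild type, the bound was also taken at higher levels. With a mean over all 6 libraries of at least 1 FPKM the phloem median lay 0.48 below it, beyond 2 standard errors of both medians combined (0.44). That cut still kept 50 xylem genes, against 29 with at least 1 FPKM in the wild type, so it did not remove the concern. At 2 FPKM or more the phloem median lay 0.32 below the bound. This was beyond 2 standard errors of the phloem median (0.25), the criterion set beforehand, but within the combined error (0.38). At 3 FPKM or more, with 14 phloem genes, the difference lay within either error. For the more abundant xylem genes the test does not decide. More xylem or fibre cells alone, a more advanced age of the leaves, or a response to the transgene may each account for the rises and were not tested.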
